A study of Homo sapiens with 2 samples.

How the data were processed

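Per the labels' protocols, total RNA of 22Rv1 cells was isolated with TRIzol, treated with DNase and made into directional libraries for paired-end sequencing, with 1 control library and 1 WCF-598 library. Poly-A status, read length and dose are not given in the sources used here. Per the submitters' processing notes, TopHat2, HTSeq and DESeq2 were used, with no versions or roles, and the builds GRCh38, hg38 and hg19 are all named. The coordinates in the deposited table are those of RefSeq genes on GRCh38, checked against a RefSeq gene table, and are printed as GRCh38. The deposited coordinates of RXRB mix sequences and are not printed.

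The deposited table has 17635 genes, each symbol on a single row. Per the file headers, it gives FPKM and TPM for each library, and the values of TPM are proportional to FPKM within a library. It also gives read counts, which are estimated counts: 28.0% of the control values and 25.4% of the WCF-598 values are exactly whole, and 32.5% and 30.0% lie within 0.01 of a whole number. The program that made these values is not given in the sources used here. The deposited normalized read counts, treated as a signal, equal the estimated counts rounded up and divided by a size factor per library, 0.940 and 1.06 in the authors' deposited table. The authors' deposited log2 fold is the log2 ratio of estimated counts without scaling for depth, with 0 replaced by 0.01. Per the file headers, the deposited p-value comes from a Poisson test, and the deposited false discovery rate exceeds 1 for 320 genes in the authors' deposited table (highest 1.01), so it was read as a score. No other per-sample columns were present.

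From the deposited FPKM, the log2 ratio of FPKM + 1 (WCF-598 over control) was computed for each gene. Genes with 1 FPKM or more in at least 1 library were kept, and a ratio of 2 or more on the FPKM + 1 scale was used as a descriptive threshold. With 1 library per group, no test and no p-value were computed. For named genes, counts scaled to the library total (CPM) were formed from the estimated counts, rounded, and their ratio was given with an exact conditional binomial 95% interval. Reads without molecular identifiers are not independent molecules, so intervals and the floor of 3 counts cover counting error only. The depths, 21139036 and 20850466 estimated counts, give narrow intervals for MYC and wide ones for genes with few counts.

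The 46 gene lists, the measure, the threshold and the rule for named genes were fixed before the data were examined. Each list with at least 3 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean log2 level. A list was said to stand outside when it fell below percentile 2.5 or above percentile 97.5. The named genes were the 15 with the largest and the 15 with the smallest log2 ratio among genes with 5 FPKM or more in at least 1 library, leaving out clone-type symbols, Y-linked genes and XIST. RXRA, RXRB, RXRG, KLK2, KLK3, TMPRSS2, FKBP5, UBE2C, MYC, FOXA1 and HOXB13 were named whatever their values, as were up to 4 members of each list described by its members with the largest absolute log2 ratio, and members in the opposite direction. MDM2, XPC, POLH, BAX, TNFRSF10B, ATF4, SLC7A5, SLC7A1, ACTB and some members in the opposite direction that were picked for size were chosen after their values were seen. Some genes and lists that these rules name are withheld and not reported here.

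Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5, median centring, TPM, trimmed mean scaling (30% of ratios and 5% of levels), upper quartile scaling, removal of the 20 highest genes, thresholds of 1.5-fold and 3-fold, and random lists unmatched or in 50 bins. Lists were also recomputed with members of 5 FPKM or more and without shared members. CPM, the authors' size factors applied to CPM, removal of the trend over GC content and level in 10 by 10 bins, random lists matched on GC content or transcript length, and the Hallmark sets annotated in the deposited table were added after the data were seen. GC content and length came from the longest protein-coding GENCODE 29 transcript of each symbol, known for 98.1% of the kept genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

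The code was tested on simulated counts for the 17635 genes with 200 changed genes. The changed genes were drawn from those with 5 FPKM or more in at least 1 library, so recovery at lower levels was not simulated. Of 50 genes seeded 4-fold higher and 50 seeded 4-fold lower, 100% passed 2-fold in the right direction. Of those seeded at 1.5-fold 0% did, and 0.0252% of 11922 unchanged genes passed 2-fold. Of 100 lists of unchanged genes 3 fell outside the central 95%, and of 100 lists shifted by 0.5 (log2) 100 did. The exact intervals held the true ratio in 94.9% of 1000 draws. The simulation holds counting error and no variation between cultures.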

Results

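RNA was sequenced from 22Rv1 cells, a human castration-resistant prostate carcinoma line. The series has 2 libraries, 1 from control cells and 1 labelled WCF-598, a compound that the series title names as a selective degrader of the retinoid X receptor gamma (RXRγ). There were no replicates, so the values below compare 2 libraries, no difference could be tested, and each interval covers counting error only. The treatment protocol recorded with both libraries instead names HX531, an antagonist of retinoid X receptors, for 48 h, and no dose is given. The groups here follow the sample labels, and the mismatch remains open. Estimated counts summed to 21139036 in the control library and 20850466 in the WCF-598 library over 17635 genes, all annotated as messenger RNA. Levels are FPKM as deposited, and log2 ratios are of FPKM + 1, WCF-598 over control, which understates the difference of genes with low levels.

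The first comparison concerned the receptor named in the title and its family. RXRG (Entrez gene 6258; GRCh38 chromosome 1, 165400922 to 165445126, minus strand) was at the limit of detection. It had 1 estimated count in the control library and 0 in the WCF-598 library, and the floor of 3 counts was equal to CPM (counts scaled to the library total) of 0.142 and 0.144. A difference in RXRG mRNA was therefore not detectable at this depth, and these data hold no measure of RXRγ protein. The authors' deposited table lists a log2 fold of −6.64 for RXRG, which follows from replacing the count of 0 with 0.01. The family members RXRB (23.9 and 23 FPKM in the control and WCF-598 libraries) and RXRA (3.78 and 3.71 FPKM) were the measured retinoid X receptors. Their CPM ratios, WCF-598 over control, of 0.950 (95% interval 0.877 to 1.03) and 0.979 (0.855 to 1.12) were within counting error of 1, and the sign of both log2 ratios depended on the scaling.

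Across the transcriptome, genes at least 2-fold higher in the WCF-598 library outnumbered those at least 2-fold lower. Of 12335 genes with 1 FPKM or more in at least 1 library, 412 were at least 2-fold higher, 35 were at least 2-fold lower and 11888 lay between. The split depended on scaling. Higher genes made up 92.2% of the 2-fold genes as deposited, 75.6% (291 higher and 94 lower) after centring on the median ratio and 77.7% (307 and 88) with trimmed mean scaling. In CPM in place of FPKM, they made up 93.7% (753 and 51) without scaling and 77.3% (501 and 147) with the authors' size factors. The median log2 ratio of all measured genes was 0.14, and median centring and trimmed mean scaling moved it by −0.14 and −0.13. The medians of lists outside the range of random lists are therefore also given relative to it. The ratio followed base composition and level across genes: the median log2 ratio was 0.29 in the tenth of genes with the lowest transcript GC content and −0.02 in the tenth with the highest. It was 0.33 in the tenth of genes with the lowest mean level and −0.16 in the tenth with the highest. The across-gene Spearman correlations with the ratio were −0.31 for GC content and −0.30 for mean level, and genes are not independent replicates.

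**Figure D1:**
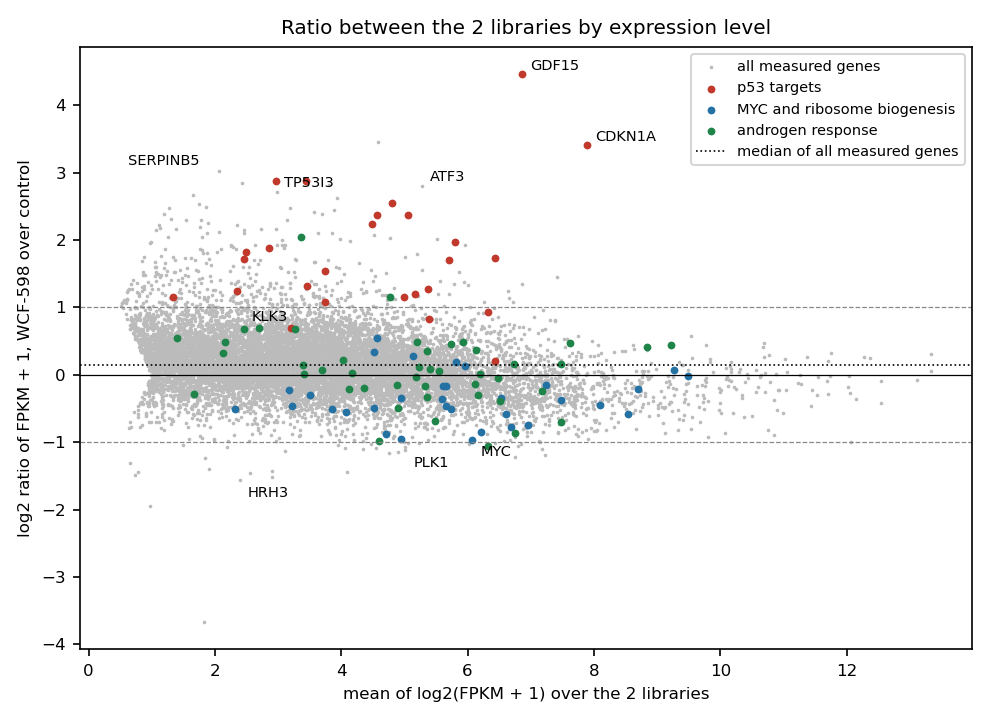
Each point is 1 of 12335 genes, with the mean of log2(FPKM + 1) over both libraries on the horizontal axis and the log2 ratio of FPKM + 1 (WCF-598 over control) on the vertical axis. Dashed lines mark 2-fold differences and the dotted line the all-gene median of 0.14; the p53 targets lie above 0, with GDF15 at 4.46 and CDKN1A at 3.41.

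The largest median difference among the gene lists fixed before the data were examined was that of p53 targets, genes that the tumour suppressor p53 activates. All 26 measured members had higher levels in the WCF-598 library, 22 of them by at least 2-fold, and none was 2-fold lower. The list's median log2 ratio was 1.71, or 1.57 above all genes, and it lay above all 10000 random lists matched on mean level (percentile 100, central 95% of random lists −0.08 to 0.25). GDF15, a secreted stress cytokine (Entrez gene 9518; chromosome 19, 18386158 to 18389176, plus strand), had the largest log2 ratio of the named genes. Its level was 23.8 FPKM in the control library and 546 FPKM in the WCF-598 library, a CPM ratio of 22.9 (21.1 to 24.9). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (Entrez gene 1026; chromosome 6, 36676463 to 36687332, plus strand), had 71.6 and 769 FPKM, a CPM ratio of 10.7 (10.4 to 11.1). TP53I3, an oxidoreductase induced by p53, had 1.88 and 20.3 FPKM, PLK3, a stress-responsive polo-like kinase, had 3 and 28.3 FPKM, and the growth arrest gene GADD45A had 10.5 and 66.8 FPKM. MDM2, the ubiquitin ligase that targets p53, had 20.2 and 46.3 FPKM. The 4 members within 2-fold were BAX (log2 ratio 0.94), TNFRSF10B (0.83), POLH (0.69) and XPC (0.20).

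Apoptosis regulators, a list of both promoters and inhibitors of cell death, were also higher as a group. Of 25 measured members, 4 were at least 2-fold higher and 0 were 2-fold lower, with a median log2 ratio of 0.51 (0.37 above all genes) at percentile 100. The 4 were the death receptor FAS (2.05 and 9.01 FPKM), the BH3-only genes PMAIP1 (5.97 and 16.4) and BBC3 (25.7 and 63.4), and the initiator caspase CASP8 (4.33 and 11.4). Of these, FAS, PMAIP1 and BBC3 are also in the p53 list. The list median gives no direction for cell death, since the inhibitors BIRC2 (log2 ratio 0.74), MCL1 (0.53) and XIAP (0.32) were higher too. In the opposite direction, the caspase inhibitor BIRC5 had a log2 ratio of −0.54, BCL2L11 of −0.30 and DIABLO of −0.11, and BAD was near 0.

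Immediate early and MAPK feedback genes, which respond rapidly to growth factor and stress signalling, formed another uniformly higher list. All 28 measured members were higher and 12 were at least 2-fold higher, with a median log2 ratio of 0.96 (0.82 above all genes) at percentile 100. The transcription factor ATF3 had 13.7 FPKM in the control library and 102 FPKM in the WCF-598 library. The AP-1 subunits JUN (6.89 and 30.8 FPKM), FOS (3.15 and 15.7) and FOSL1 (0.69 and 4.65) had log2 ratios of 2.01, 2.01 and 1.74.

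Stress-response lists differed among themselves. In the integrated stress response list, 7 of 34 measured members were at least 2-fold higher and 0 were 2-fold lower, with a median log2 ratio of 0.26 (0.12 above all genes) at percentile 99.9. GDF15 and ATF3 led this list, followed by PPP1R15A (12.6 and 54.4 FPKM), a phosphatase subunit that restores translation, and DDIT3 (31.0 and 121 FPKM), which encodes CHOP. The amino acid transporters SLC7A5 (538 and 307 FPKM) and SLC7A1 (22.5 and 13.01 FPKM) were lower, and ATF4 itself had 324 and 315 FPKM. Against random lists not matched on level, this list lay at percentile 93.0, inside the central 95%. NRF2 oxidative stress targets had 4 of 22 members at least 2-fold higher and a median of 0.28 (0.14 above all genes) at percentile 99.6. They included the haem-degrading enzyme HMOX1 (2.88 and 20.7 FPKM), NQO1 (12.9 and 37.3), the transporter ABCC2 (0.64 and 3.35) and the autophagy receptor SQSTM1 (66.6 and 148). The pentose phosphate enzymes TKT, TALDO1 and PGD in this list had log2 ratios of −0.76, −0.68 and −0.40. Its percentile was 92.2 against unmatched random lists and 86.9 without members shared with other lists. The unfolded protein response of the endoplasmic reticulum (median −0.00, percentile 42.8) and the heat shock list (−0.09, percentile 37.4) lay within the central 95%.

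Genes of the interferon response and of autophagy were higher too. Of 26 measured interferon response genes, 6 were at least 2-fold higher and 0 were 2-fold lower, with a median of 0.61 (0.47 above all genes) at percentile 100. HLA-B, an antigen-presenting molecule whose reads can be shared with its paralogs, had 8.85 and 24.9 FPKM. ISG20 had 3.89 and 10.9 FPKM, IRF9 2.77 and 7.15 FPKM, and GBP1 0.48 and 2.14 FPKM. CMPK2 (−0.11) and OAS3 (−0.08) had log2 ratios below 0. Among 30 autophagy and lysosome genes, GABARAPL1 (10.0 and 33.6 FPKM) and SQSTM1 were the 2 at least 2-fold higher. Relative to the all-gene median GABARAPL1 alone passed 2-fold. The list median was 0.38 (0.23 above all genes) at percentile 99.97. MAP1LC3B, which encodes an autophagosome membrane protein, had a log2 ratio of 0.73 and ATG12 of 0.71, while the lysosomal protease CTSL had −0.58 and the proton pump subunit ATP6V0D1 −0.39.

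The MYC and ribosome biogenesis and the cholesterol biosynthesis lists were lower. In the MYC and ribosome biogenesis list, 29 of 33 measured members lay below the median of all genes. The list median was −0.38 (−0.52 relative to all genes) at percentile 0. On the deposited scale 0 members passed 2-fold, and relative to the all-gene median 3 members, MYC, BOP1 and RRP9, were at least 2-fold lower. MYC itself (Entrez gene 4609; chromosome 8, 127735434 to 127742951, plus strand) had 93.2 FPKM in the control library and 47.3 FPKM in the WCF-598 library, a CPM ratio of 0.506 (0.486 to 0.527). The nucleolar proteins BOP1 (41.7 and 21.1 FPKM) and RRP9 (34.5 and 18.3) and the spermidine synthase SRM (98.5 and 54.5) were next. RRP12 (0.54), WDR43 (0.34) and NOP58 (0.29) had log2 ratios above 0. Cholesterol biosynthesis genes had a median of −0.41 (−0.56 relative to all genes) at percentile 0, with 20 of 27 members below 0, 0 past 2-fold and 1, SQLE, at least 2-fold lower relative to the all-gene median. SQLE, the squalene epoxidase, had 20.6 and 10.7 FPKM, EBP 155 and 88.3 FPKM, DHCR7 72.3 and 42.9 FPKM, and FDFT1 327 and 202 FPKM. HSD17B7 (0.66), STARD4 (0.59), TM7SF2 (0.58), GGPS1 (0.46) and SC5D (0.41) went the other way. Nuclear-encoded oxidative phosphorylation genes had a median of −0.26 (−0.41 relative to all genes) at percentile 2.47, with NDUFB7 (148 and 77.7 FPKM) as the largest difference and UQCRB (0.27) among the 5 members above 0, and 4 of 17 alternative settings placed the list inside the central 95%.

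Cell cycle genes were mixed. The G1/S and DNA replication list had a median of −0.19 (−0.34 relative to all genes) at percentile 0.09. UHRF1, which maintains DNA methylation at replication, was the 1 member of 42 that was at least 2-fold lower on the deposited scale (33.2 and 15.2 FPKM). The uracil glycosylase UNG (196 and 98.3 FPKM), the replication factor GINS2 (46.8 and 24.2) and the helicase subunit MCM6 (38.0 and 19.8) were close to 2-fold lower and passed it relative to the all-gene median. CCNE2 (0.76), RRM2 (0.72), PRIM1 (0.52) and DTL (0.50) had log2 ratios above 0. The G2/M and mitosis list had a median of −0.06 at percentile 8.83, inside the central 95%, and lay at percentile 0.13 when random lists were matched on GC content as well. Within it the mitotic kinase PLK1 (46.6 and 20.99 FPKM), the anaphase activator CDC20 (133 and 66.9) and securin, encoded by PTTG1 (232 and 128), were lower, while the kinase CDK1 was higher (59.2 and 119 FPKM). UBE2C, a mitotic ubiquitin-conjugating enzyme, had 145 and 128 FPKM.

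**Figure D2:**
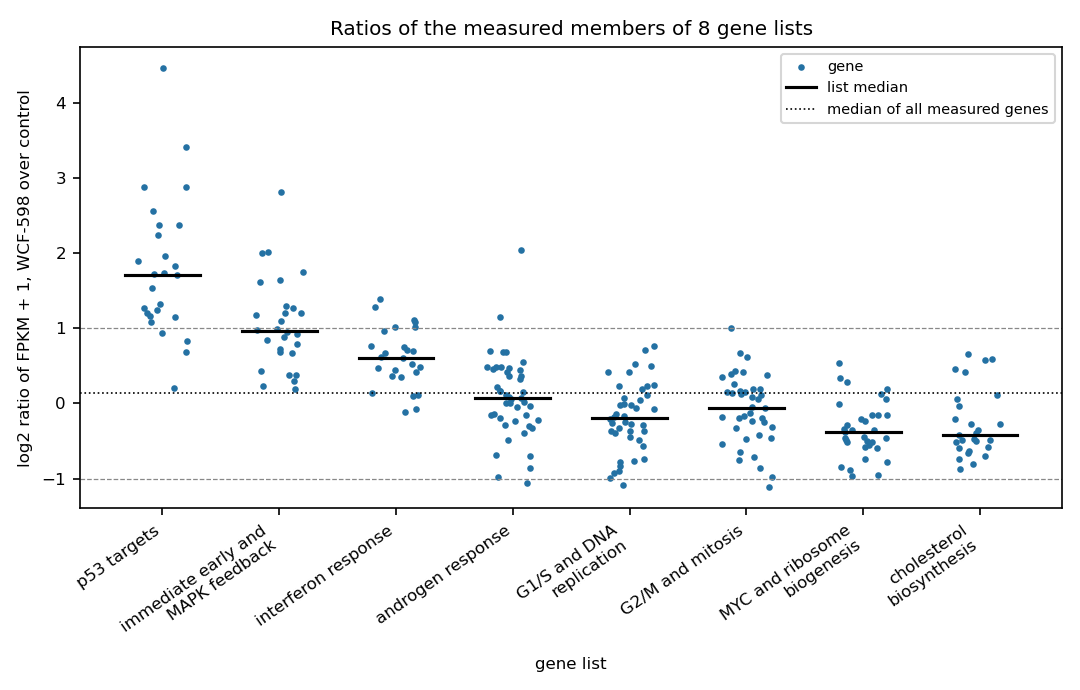
Points are the log2 ratios of FPKM + 1 (WCF-598 over control) of the measured members of 8 gene lists, with a black bar at each list median. Dashed lines mark 2-fold differences and the dotted line the all-gene median; the p53 list (median 1.71) and the immediate early list (0.96) lie above 0 throughout, and the androgen response list (0.07) spreads to both sides.

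Androgen response genes went both ways. Of 45 measured members, 2 were at least 2-fold higher, 1 was at least 2-fold lower and 27 had log2 ratios above 0. The list median was 0.07 (−0.07 relative to all genes) at percentile 78.4 of the random lists, inside the central 95%. Its sign turned under median centring (−0.07), trimmed mean scaling (−0.06) and the authors' size factors applied to CPM (−0.06). KLK3, which encodes prostate-specific antigen, had 3.33 and 5.95 FPKM, a CPM ratio of 1.80 (1.41 to 2.30). KLK2 (ratio 1.01, 0.896 to 1.14), TMPRSS2 (1.02, 0.941 to 1.11) and FKBP5 (1.004, 0.967 to 1.04) did not differ beyond counting error, and their small log2 ratios change sign with the scaling. KLK2 and KLK3 are paralogs whose reads can be shared. TARP, which lies within the T-cell receptor gamma locus (4.06 and 19.8 FPKM), and TSC22D1 (17.4 and 39.7 FPKM) were the higher pair. The desaturase SCD (115 and 54.9 FPKM) was 2-fold lower, and the transporter SLC45A3 (33.0 and 16.2 FPKM), with a log2 ratio of −0.98, was just short of that. Among transcription factors of the prostate lineage, GATA2 (105 and 64.5 FPKM), the pioneer factor FOXA1 (95.1 and 69.4) and HOXB13 (145 and 123) were lower, and ETV1 was higher (2.83 and 6.34 FPKM).

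Lists tied to partners of retinoid X receptors were compared next. Retinoic acid receptor targets had a median of 0.57 (0.42 above all genes) at percentile 99.1. At least 2-fold higher were 2 of 11 members, PLAAT4 (0.13 and 1.62 FPKM) and the retinaldehyde reductase DHRS3 (7.81 and 18.4 FPKM). PLAAT4 rests on 2 and 24 estimated counts, and it alone passed 2-fold relative to the all-gene median. The retinoic acid carrier CRABP2 had 104 and 203 FPKM, while RAI1 had a log2 ratio of −0.48. PPAR targets had a median of 0.30 (0.16 above all genes) at percentile 98.0, with the redox regulator TXNIP at 102 and 280 FPKM and FABP3 (−0.15) and PLIN4 (−0.14) below 0. The 2 lists fell inside the central 95% in 4 and 7 of 17 alternative settings. Liver X receptor targets had a median of −0.01 at percentile 26.6, with APOE higher (2.71 and 8.16 FPKM) and SCD and SREBF1 (44.2 and 21.6 FPKM) lower. The receptors that partner with retinoid X receptors and the steroid receptors had a median of 0.21 at percentile 55.8. At least 2-fold higher were 4 of 26, with NR4A1, NR1D1 and NR1H4 among them, and 2 relative to the all-gene median. The 4 measured vitamin D and thyroid receptor targets, which include CDKN1A, had a median of 0.27 at percentile 87.7.

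Among the other single genes, SERPINB5, the epithelial serpin maspin, had 0.47 and 10.96 FPKM, a CPM ratio of 23.5 (15.8 to 36.7). DRAM1, a lysosomal regulator of autophagy that p53 induces, had 2.09 and 19.3 FPKM. The riboflavin transporter SLC52A1 (1.02 and 13.5 FPKM), FAXDC2 (4.25 and 36.2), the actin-severing protein gelsolin, encoded by GSN (5.19 and 37.0), and the stathmin family gene STMN4 (0.40 and 7.15) were also among the 15 largest positive log2 ratios. TRIM49 (0.25 and 6.97 FPKM) and the glucuronosyltransferase UGT2B11 (0.52 and 7.57 FPKM) belong there too but share sequence with close paralogs, so their values are uncertain. The largest negative log2 ratio among the named genes was that of the histamine receptor HRH3 (8.01 and 2.05 FPKM), with a CPM ratio of 0.257 (0.208 to 0.317). DHRS2 (11.6 and 3.40 FPKM), the MAP kinase phosphatase DUSP9 (8.74 and 2.55), the chemokine receptor ACKR3 (11.3 and 3.56) and the globin gene HBQ1 (27.1 and 9.31) followed. At higher levels, HSD11B2, which inactivates cortisol, had 163 and 69.1 FPKM, NAA38 224 and 97.9 FPKM, and the purine salvage enzyme APRT 211 and 98.3 FPKM. The remaining genes with the largest negative log2 ratios were MATK (−1.15), ANAPC15 (−1.14), PHF21B (−1.14), the DNA glycosylase NTHL1 (−1.10) and the neuropeptide gene GAL (−1.09).

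Markers of other cells and of RNA quality, and epithelial-mesenchymal transition genes, differed as well. The 7 measured fibroblast and smooth muscle markers had a median of 0.71 (0.56 above all genes) at percentile 99.3, with ACTA2 at 2.15 and 13.1 FPKM and LUM at 20.7 and 34.4 FPKM, and COL3A1 (−0.34) below 0. Epithelial-mesenchymal transition genes had a median of 0.38 (0.24 above all genes) at percentile 98.9. MMP14 (2.15 and 7.21 FPKM) had the largest difference, and L1CAM (−0.26) lay below 0. The list pools mesenchymal and epithelial genes, so its median gives no direction of a transition. Its epithelial genes KRT19 (0.80), CLDN7 (0.53) and CLDN4 (0.41) were also higher, and CLDN3 (−0.13) was lower. Immune cell markers had 4 measured members and a median of −0.30 (−0.45 relative to all genes) at percentile 0.71. CD68 was higher (1.29 and 5.34 FPKM), and LYZ (2.03 and 0.72 FPKM) and the globin gene HBA1 (27.5 and 17.3 FPKM) were lower. The 13 mitochondrially encoded mRNAs had a median of 0.25 (0.11 above all genes) at percentile 99.99 and took 5.27% of counts in the control library and 5.84% in the WCF-598 library. Among them MT-ND6 had a log2 ratio of 0.57 and MT-ATP6 of −0.42. The 13 measured histone genes had a median of −0.06 (−0.20 relative to all genes) at percentile 1.12. Some alternative setting placed each of these 5 lists inside the central 95%. Housekeeping references had a median of −0.13 at percentile 41.3, with ACTB at 2271 and 1583 FPKM.

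**Figure D3:**
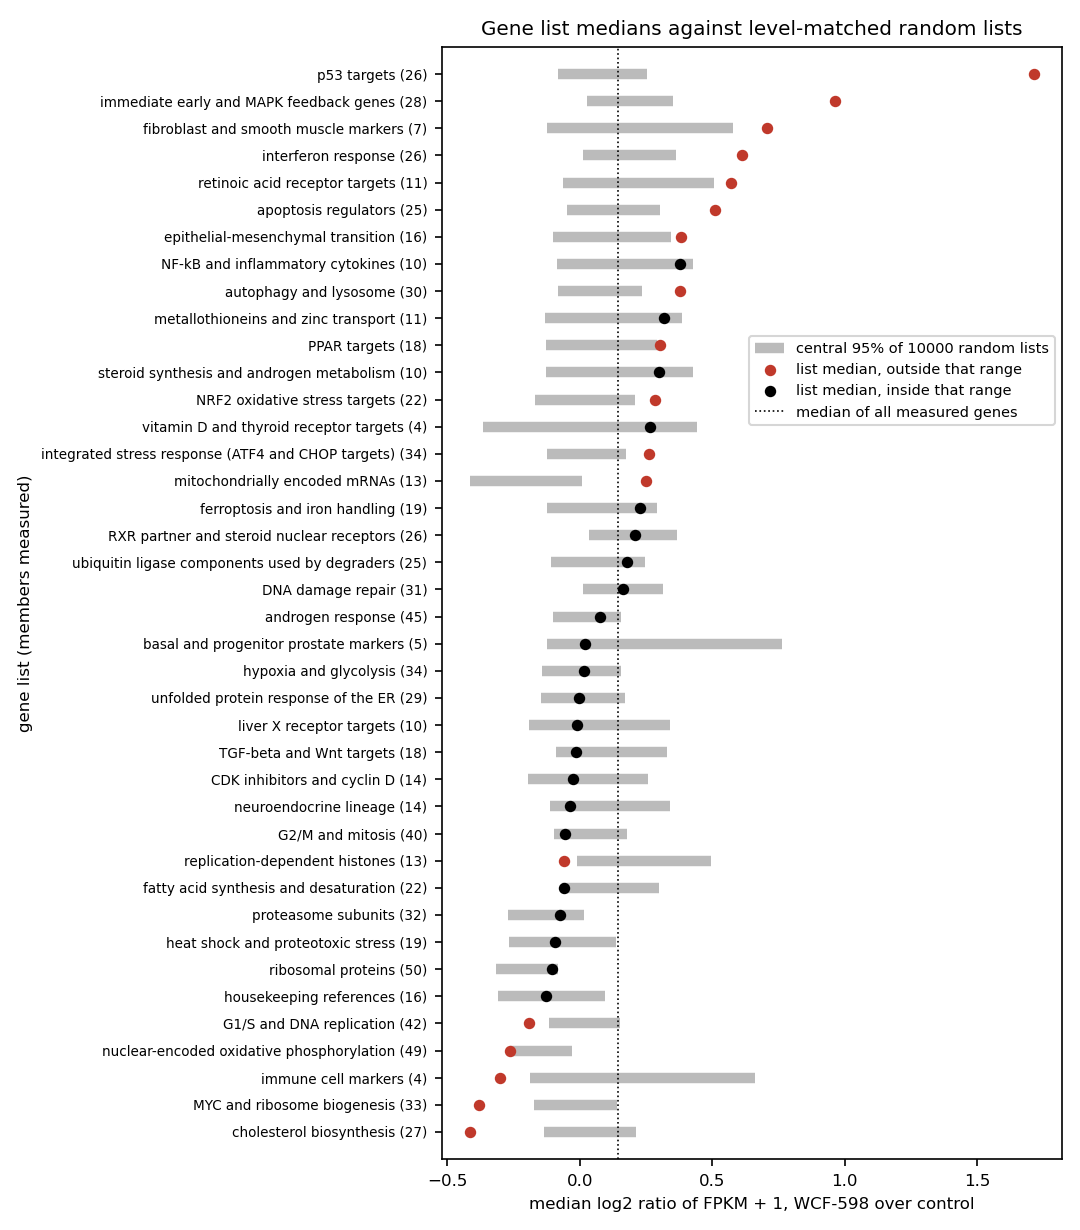
Dots are the median log2 ratios of FPKM + 1 (WCF-598 over control) of 40 gene lists with at least 3 measured members, and grey bars the central 95% of 10000 random lists matched on mean level. Red dots mark the 18 of these outside that range, 12 above and 6 below, and the dotted line is the all-gene median.

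In total, 43 of the 46 fixed lists had at least 3 measured members. Of these, 13 lay above and 7 below the central 95% of their random lists, and 23 lay inside. By chance 2.15 lists would fall outside if genes within a list varied independently, as those of the random lists do. Genes that vary together between single cultures can place more lists outside, so the excess over 2.15 is no evidence of a treatment effect. Counts of members past 2-fold also depend on the scale: relative to the all-gene median they were 21 higher for p53 targets, 11 for immediate early genes, 6 for the integrated stress response, 4 for apoptosis regulators, 3 for NRF2 targets and 2 for the interferon response, and 3 lower for androgen response genes and for the G2/M list. The lists inside the range that have not been named above included CDK inhibitors and cyclin D (median −0.03), DNA damage repair (0.16), ubiquitin ligase components used by degraders (0.18), proteasome subunits (−0.07), ribosomal proteins (−0.11) and hypoxia and glycolysis (0.02). They also included fatty acid synthesis and desaturation (−0.06), steroid synthesis and androgen metabolism (0.30), ferroptosis and iron handling (0.23) and metallothioneins and zinc transport (0.32). Also inside were NF-kB and inflammatory cytokines (0.38), TGF-beta and Wnt targets (−0.02), neuroendocrine lineage (−0.04) and basal and progenitor prostate markers (0.02). The authors' deposited table lists 1481 genes at least 2-fold higher and 166 at least 2-fold lower at a false discovery rate of 0.05 or less from a Poisson test, of which 616 and 78 had less than 1 FPKM in both libraries. Of the 412 and 35 genes above, 407 and 32 are among them. That rate compares the reads of 2 libraries, not the conditions, and the authors' deposited values put 54.1% of all genes at a rate of 0.05 or less.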

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

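The pseudocounts, filters, scalings, thresholds and most list settings were planned; CPM, the authors' size factors, trend removal and matching on GC content or transcript length were chosen after the data were seen. The numbers of genes at least 2-fold higher and lower, 412 and 35 as reported, depended on the setting. They were 837 and 86 with a pseudocount of 0.1, 116 and 9 with a pseudocount of 5, 1679 and 407 at 1.5-fold and 112 and 2 at 3-fold. Genes higher numbered 270 with a filter of 5 FPKM, 730 in TPM and 753 in CPM. Genes lower numbered 94 after median centring, 88 with trimmed mean scaling, 56 with upper quartile scaling, 147 with the authors' size factors applied to CPM and 19 after removal of the trend over GC content and level. Pseudocounts, filters and thresholds change these counts by construction. Scalings do so too, because they shift the ratios of all genes. The all-gene median moved by −0.14 with median centring, −0.13 with trimmed mean scaling and −0.07 with upper quartile scaling. Which scaling is right was not tested, and neither was the cause of the change with CPM in place of FPKM. More genes were higher than lower in each of these settings. The RXRG value, from 1 and 0 counts, stayed under the floor, the androgen response list stayed inside the central 95% of random lists (percentile 14.99 to 91.2) and the p53 list stayed above all of them (median 1.17 to 1.83) in the alternatives run.

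No list that stood outside the central 95% crossed to the opposite side. Of 724 alternative list values, 44 brought an outside list inside and 20 took an inside list outside. The 8 lists of 20 that stayed outside in all alternatives run were p53 targets, immediate early genes, apoptosis regulators, interferon response, autophagy and lysosome, MYC and ribosome biogenesis, cholesterol biosynthesis and G1/S and DNA replication. None of the 30 named genes at least 2-fold different changed sign among their 330 alternative values. That outcome was largely fixed in advance. Pseudocounts and filters cannot change a sign, and the scalings were too small to reverse a 2-fold difference. Restricting to messenger RNA and keeping a single row per symbol gave no separate values, since the table already meets both. No paired analysis was possible because each group has 1 library. Depth limits RXRG and genes with few counts, such as TRIM49, whose interval for the CPM ratio ran from 15.5 to 57.1.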

Other observations

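All values and tests in this part were chosen after the results were seen. Among the 50 Hallmark sets annotated in the table, 18 lay above and 5 below the central 95% of random lists matched on level. The p53 pathway set had 50 of 181 measured genes at least 2-fold higher (median log2 ratio 0.47), and the set of TNF signalling through NF-kB had 35 of 149 (0.54), both at percentile 100. The apoptosis (28 of 129), hypoxia (25 of 168) and xenobiotic metabolism (20 of 137) sets were also at percentile 100, whereas the fixed hypoxia and glycolysis list was at percentile 57.5. Below the range lay the second MYC target set (median −0.38), the G2/M checkpoint set (−0.11) and the E2F target set (−0.10). The Hallmark androgen response set was at percentile 85.4.

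Several single genes outside the naming rule also differed. The xenobiotic-metabolizing enzyme CYP1A1 had 4.68 FPKM in the control library and 28.8 FPKM in the WCF-598 library, and the Wnt antagonist DKK1 had 4.15 and 26.6 FPKM. The androgen-conjugating enzyme UGT2B15 had 16.5 and 58.2 FPKM and UGT2B7 0.54 and 6.58 FPKM, with reads that can be shared among paralogs. The growth factor gene AREG had 0.76 and 6.6 FPKM, the secreted protein gene AGR2 1.64 and 10.4 FPKM, and the lysosomal glycoprotein gene GPNMB 1.35 and 9.95 FPKM. Lower single genes with high levels were TMSB10, at 6048 and 3038 FPKM, and TUBA1B, at 2504 and 1344 FPKM. The transcript LOC128031835 had 11.7 and 0 FPKM from 5.68 and 0 estimated counts, so its log2 ratio of −3.67 rests on few reads.

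The higher p53 targets may reflect a p53 response in the treated cells, which was not tested. After the trend over GC content and level was removed, the list median still lay 1.54 (log2) above all genes, which argues against that trend as the whole cause. Fibroblast, immune or endothelial cells in the WCF-598 library stay open as a partial cause. The most increased of their markers, LUM, gained 13.7 FPKM, and 2 of 26 measured p53 targets, GDF15 and CDKN1A, gained more than 10 times that, while the median gain of a p53 target was 25.7 FPKM. The fibroblast and smooth muscle list itself lay at percentile 99.3, although COL3A1 was lower (2.52 and 1.79 FPKM) and COL1A2 stayed at 0.25 and 0.35 FPKM. The immune marker list lay below the range, at percentile 0.71, and no endothelial marker gained more than 0.11 FPKM. The immune list has 4 measured members that went both ways and include the globin gene HBA1, so its percentile says little about immune cells. A difference between the cultures unrelated to the compound cannot be told apart from a response to it, because there was 1 library per group, and neither can the compounds named in conflict by the labels.

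The excess of higher over lower genes might come from scaling, from the trend over GC content and level, or from noise in genes with few reads. Higher genes remained 75.6% of the 2-fold genes after median centring and 83.3% (255 higher, 51 lower) after the trend was removed and ratios were centred. Among 10925 measured genes with 100 or more estimated counts in each library they made up 90% (234 higher, 26 lower), without centring. Each value lies above a 60% bound, but that bound was set after the results were seen, so the bound excludes none of these causes. In the simulated counts, counting error alone put 0.0252% of 11922 unchanged genes past 2-fold. In the data 3.34% of measured genes were at least 2-fold higher and 0.284% at least 2-fold lower. These values argue against counting error as the source of the excess, but the simulation holds no other noise between libraries. An excess of higher genes remained after median centring, after trend removal with centring and among genes with 100 or more estimated counts. Part of it does depend on scaling. No biological explanation was tested for this pattern.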
